A study of Mus musculus with 10 samples.

How the data were processed

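Total RNA of WT and Sirt6 KO mouse samples at 0, 1.5, 6 and 24 h of TNF-alpha was labelled with Cy5 and hybridised against a universal mouse reference RNA in Cy3 on 10 two-colour arrays, per the labels. The samples formed 8 groups of genotype and time, with 2 arrays at 0 h and 1 at each later time. The deposited values are 1 log ratio per spot, normalized by the authors in a way not given in the sources used here, and are read as log2 of Cy5 over Cy3. Neither the base nor the direction is stated in the labels. The values run from -8.23 to 8.97, too wide for log10, and known TNF-alpha targets are higher on treated arrays under this reading. If the base were another, the fold changes would differ and the directions and tests would not.

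Spots with a value on all 10 arrays were kept (36113 of 38784, with 36822 to 38556 values per array). A probe was assigned to a gene where the platform table gave 1 symbol, as for 22204 probes, and 16580 probes without a single symbol were tested apart, 14916 of them with complete values. Of these 0 passed in any comparison (limma, 471 to 1903 at an unadjusted p under 0.05). Array medians lay between -0.255 and -0.004, and each array was centred on its median over genes. A gene is the mean of its probes, and 9794 of the 14365 genes tested had 1 probe. Correlations between arrays ranged from 0.441 to 0.804 over spots. The 0 h pair correlated at 0.804 in WT but at 0.601 in KO, lower than KO 0 h array a with WT 0 h array a (0.671). The number of arrays limits the precision.

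Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, and a Benjamini-Hochberg adjusted p under 0.05 within each of 8 comparisons. The genotype average and the TNF responses came from an additive model of genotype and time (5 residual degrees of freedom, prior 3.64). Its residuals hold both the spread of the 0 h pairs and any difference in response between the genotypes. The genotype average weights each time by its arrays, so 0 h, with 2 per genotype, counts more than each later time with 1. Genotype at 0 h, the interactions and the responses of each genotype came from a model with 1 mean per group (2 residual degrees of freedom, prior 3.33), whose spread comes from the 0 h pairs alone. Gene lists, 29 lists of 781 genes, were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry. The adjusted p of camera is over the lists of 1 comparison. The results of fry are given only where stated.

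The comparisons, the lists, most alternatives and the rule for named genes were chosen before the data were examined. By that rule Sirt6, Tnf, Nfkbia, Icam1, Birc3, Sod2 and Igf1 could be named always, as could the 8 called genes with the largest rise and the 8 with the largest fall whose direction held in every pairing of arrays, and up to 4 called members per list. Where fewer than 5 genes were called, members of the first 4 lists with the largest absolute change were to be named and described as not passing. How many, 5 per list at most, was set later. Only some of these members are given, and few in the interactions. Members that passed adjusted over the list alone but fall outside this rule were named after their values were seen, as were examples from the other lists. Clone, model and unnamed symbols were counted and not named.

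The tests were tried on simulated data, drawn for all 10 arrays from a normal distribution with each gene's moderated variance, with changes added to 200 genes. The simulated genes were independent and all arrays varied alike, which the real data need not do. A log2 change of 2 was recovered for 98% of the genes in the genotype average, 80.5% at 0 h and 93.5% to 98.5% in the TNF responses, and for 0 in the interactions. A log2 change of 4 was recovered for 90.5% to 96% in the interactions, and a change of 1 for 72.5% in the genotype average and 0 elsewhere. Recovery in the real data can be lower. In the TNF response at 1.5 h Cxcl1 (log2 2.83, adjusted p = 0.210) and Ccl20 (2.81, 0.449) did not pass by limma.

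Alternatives, tried 1 at a time, were values without centring, quantile normalization, probes with values on at least 8 arrays, each probe alone, only genes with an SD above the median, a robust variance prior, letters a and b as a replicate block, an adjusted p under 0.1, a minimum log2 change of 1, the other model, 1 average interaction, and each array left out in turn. Added after seeing the data were removal of the local trend in spot order (a running median over 101 spots), scaling of arrays to equal range, array weights, and leaving out the WT 24 h array together with KO 0 h array b. No sample was left out of the results given first.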

Results

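Gene expression was measured on 10 two-colour arrays in wild-type (WT) and Sirt6 knockout (KO) mouse samples, untreated (0 h) and after 1.5, 6 and 24 h of TNF-alpha. TNF-alpha is an inflammatory cytokine that activates the transcription factor NF-kB. Sirt6 encodes a chromatin-bound deacetylase, and the design addresses whether its loss changes the response of NF-kB target genes to TNF-alpha. Each genotype had 2 arrays at 0 h, a and b, and 1 array at each later time. The cell type is not given in the sources used here, nor is it stated whether a and b were separate cultures. The errors and p-values therefore measure only the spread between these samples, which may be technical. In the genotype average and the TNF responses this spread includes any difference in response between the genotypes, which counts there as error. Each array compared the sample, in Cy5, with a universal mouse reference RNA, in Cy3. Of 38784 spots, 36113 had a value on all 10 arrays, and 14365 genes were tested. The number of arrays limits the precision. The treated arrays have no replicates. The comparisons that use 1 treated array per genotype assume that it varied like the 0 h pairs.

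Sirt6 was measured by 2 probes, whose mean was lower in KO than in WT at 0, 1.5 and 6 h. The WT arrays lay between -0.16 and 0.07 on the log2 scale. The KO arrays lay at -1.05 and -0.82 at 0 h, at -0.76 at 1.5 h and at -1.16 at 6 h. The array labelled KO at 24 h lay at -0.05, within the WT range. KO minus WT was -0.88 (SE 0.21, n = 2 per genotype) at 0 h, -0.60 (SE 0.30) at 1.5 h, -1.23 (SE 0.30) at 6 h and 0.11 (SE 0.30) at 24 h. The genotype average, in which 0 h weighs more than each later time, was -0.70 (SE 0.20), with an adjusted p of 0.428 from limma over all genes. Its direction held at 3 of 4 times. The probes differed in size, with means of -0.44 and -0.96, and it is not known whether they lie in the deleted part of the gene. Every comparison that uses the array labelled KO at 24 h carries this doubt about its label.

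**Figure D1:**
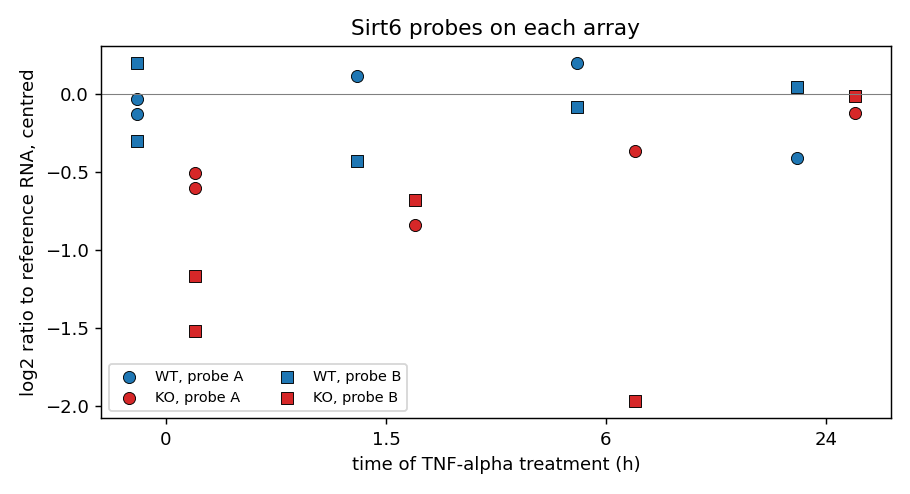
Level of the 2 Sirt6 probes (circles and squares) on each of the 10 arrays, as the centred log2 ratio to the reference RNA, against hours of TNF-alpha treatment, with WT in blue and KO in red. Both probes lie lower on the KO arrays at 0, 1.5 and 6 h, and at -0.12 and -0.01 on the array labelled KO at 24 h.

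The first question was which genes responded to TNF-alpha in the mean over the genotypes. In the TNF response at 1.5 h, the mean over the genotypes against 0 h, the chemokine Ccl2, which attracts monocytes, rose 7.15-fold (log2 2.84, SE 0.23, adjusted p = 0.0107). It was the only one of the 14365 genes to pass over all genes, against 536 at an unadjusted p under 0.05, where 718 would be reached by chance. With the model of 1 mean per group or with letters as a replicate block 0 genes passed, and after removal of the trend in spot order 4 did. The list of chemokines and cytokines rose as a group, with a median of 0.39 in 30 measured genes (camera adjusted p = 4.12e-07, and adjusted p = 0.0428 with an estimated correlation). The median was 0.16 without KO 0 h array b. Of its members 9 rose and none fell, adjusted over the list alone. Among them were the neutrophil chemokine Cxcl1 (log2 2.83, SE 0.39), Ccl20 (2.81, SE 0.47), Ccl7 (1.50, SE 0.18) and Cxcl5 (1.41, SE 0.34). The list of NF-kB pathway and feedback genes also rose, with a median of 0.27 in 26 genes (camera adjusted p = 1.03e-07, but adjusted p = 0.225 with an estimated correlation). Adjusted over the list alone, 6 of its members rose: Bcl3 (1.51, SE 0.20), Nfkbia, which encodes the NF-kB inhibitor IkB-alpha (1.40, SE 0.22), the feedback inhibitor Tnfaip3 (0.91, SE 0.22), Ikbke (0.85, SE 0.19), Nfkb2 (0.82, SE 0.16) and the apoptosis inhibitor Birc3 (0.82, SE 0.23). Without the KO 1.5 h array Tnfaip3 was at 0.60 and Birc3 at 0.41, and without the WT 1.5 h array Birc3 was at 1.24. The immediate early list had a median of 0.19 (adjusted p = 0.0148) and the smooth muscle list one of -0.23 (adjusted p = 0.0203), each with adjusted p = 0.763 with an estimated correlation. By limma 0 of their members passed adjusted over the list alone, with 3 and 2 at an unadjusted p under 0.05. The immediate early list no longer passed without KO 0 h array b (median 0.11, adjusted p = 0.337) or the KO 1.5 h array (0.13, 0.134). The smooth muscle list did not without KO 0 h array a (-0.16, 0.0584), KO 0 h array b, where its median was larger in size (-0.38, 0.337), or the WT 1.5 h array (-0.070, 0.583). Icam1, which encodes an adhesion molecule (0.91, SE 0.53), Tnf (0.23, SE 0.29) and Sod2 (-0.21, SE 0.18) did not pass. The value of Tnf is a mean of opposite ones, 0.80 in WT and -0.35 in KO (SE 0.23 each), and that of Icam1 of 0.17 and 1.64 (SE 0.35 each). Ccl2 ceased to pass without WT 0 h array a, WT 0 h array b, KO 0 h array a or the KO 1.5 h array, which left 0 genes. Without the WT 1.5 h array 4 genes passed.

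In the TNF response at 6 h, Ccl2 was 7.44-fold higher (log2 2.90, SE 0.23, adjusted p = 0.00901) and Ccr1l1, a chemokine receptor-like gene, 3.71-fold lower (log2 -1.89, SE 0.19, adjusted p = 0.0355) than at 0 h. These were the 2 genes past the threshold over all genes, against 413 at an unadjusted p under 0.05. With letters as a replicate block 0 passed, and 1 did without centring, with each probe alone or with the model of 1 mean per group. Chemokines and cytokines rose as a group (median 0.15, camera adjusted p = 5.09e-07, and adjusted p = 0.0387 with an estimated correlation), with a median of 0.097 without KO 0 h array b and 0.26 without the WT 6 h array. Of its members 8 rose and none fell, adjusted over the list alone, among them Ccl20 (2.91, SE 0.47), Cxcl1 (1.90, SE 0.39) and Cxcl5 (1.77, SE 0.34). The NF-kB list had a median of 0.31 (camera adjusted p = 5.80e-07, but adjusted p = 0.197 with an estimated correlation), and one of 0.19 without KO 0 h array b. Of its members 5 rose, adjusted over the list alone: Nfkbia (1.32, SE 0.22), Nfkb2 (1.13, SE 0.16), Bcl3 (0.89, SE 0.20), Nfkbie (0.79, SE 0.21) and Ikbke (0.77, SE 0.19). The list of inflammatory effectors, secreted and surface proteins of the acute response, was higher at this time in the mean over the genotypes. Its median was 0.36 and 22 of 29 members were positive (camera adjusted p = 1.03e-05, and adjusted p = 0.0387 with an estimated correlation). Some members moved in opposite directions by genotype. Lcn2 was at -1.80 in WT and 3.20 in KO, Lbp at -1.25 and 1.94, and Cp at -1.13 and 1.07. Has2, at 0.64 in WT and -0.39 in KO, and Ch25h, at 0.74 and -0.23, went the other way. None of the effectors passed alone, with 4 at an unadjusted p under 0.05. The largest values were those of Nos2 (1.40, SE 0.48), whose 2 probes gave 3.17 and -0.36, and of the matrix protease Mmp3 (1.39, SE 0.63). Both came mostly from KO, with 0.52 in WT and 2.28 in KO for Nos2 (SE 0.42 each) and 0.11 and 2.67 for Mmp3 (SE 0.60 each). Without the KO 6 h array they were 0.37 and 0.62, and without the WT 6 h array 2.43 and 2.16. Mmp3 was at 0.85 without KO 0 h array a. Without the KO 6 h array the effector list no longer passed, with a median of 0.28 and an adjusted p of 0.0874. The muscle list had a median of -0.27 (adjusted p = 0.0171, but adjusted p = 0.242 with an estimated correlation). It became 0.03 without the KO 6 h array and was -0.25, with an adjusted p of 0.150, without KO 0 h array b. The cell cycle list had a median of 0.09 (adjusted p = 0.0467, but adjusted p = 0.702 with an estimated correlation). It no longer passed without either KO 0 h array, either 1.5 h array or the KO 6 h array (adjusted p from 0.0538 to 0.644). Its median was the same without a 1.5 h array, 0.081 without the KO 6 h array, 0.14 without KO 0 h array a and 0.056 without b. Leaving out 1 array at a time changed the number of genes past the threshold in every case. It was 0 without WT 0 h array a, WT 0 h array b, the WT 6 h array or KO 0 h array a, 9 without the KO 6 h array, and 1, which was Ccl2, without any of the other 5.

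In the TNF response at 24 h, which uses the array labelled KO at 24 h, Ccl2 (8.67-fold, log2 3.12, SE 0.23, adjusted p = 0.00491) and the related chemokine Ccl7 (3.45-fold, log2 1.79, SE 0.18, adjusted p = 0.0409) were higher than at 0 h. These were the 2 genes past the threshold, against 1017 at an unadjusted p under 0.05. With letters as a replicate block 0 passed, without centring or with each probe alone 1, and with the model of 1 mean per group 5. Chemokines and cytokines had a median of 0.22 (camera adjusted p = 0.000567, but adjusted p = 0.136 with an estimated correlation), and of 0.13 without the array labelled KO at 24 h and 0.36 without the WT 24 h array. Of its members 8 rose and none fell, adjusted over the list alone, among them Cxcl5 (2.55, SE 0.34), Ccl20 (2.15, SE 0.47), Cxcl1 (2.01, SE 0.39) and the growth factor Csf1 (1.02, SE 0.22), the last named after its value was seen. The NF-kB list had a median of 0.23 (adjusted p = 0.0114, but adjusted p = 0.608 with an estimated correlation). Of its members Nfkbia (1.3, SE 0.22), Bcl3 (0.95, SE 0.20), Nfkb2 (0.82, SE 0.16) and Ikbke (0.79, SE 0.19) rose, adjusted over the list alone. Members of other lists also rose when adjusted over the list alone. These were Ier3 of the immediate early genes (0.98, SE 0.21), the macrophage markers Lyz2 (0.74, SE 0.20), Cybb (0.75, SE 0.22) and Tyrobp (0.60, SE 0.18), and the cartilage proteoglycan Acan (1.21, SE 0.31). Lyz2 was at 0.49 without the array labelled KO at 24 h. The macrophage list as a group did not pass by camera, and some of its members moved in opposite directions by genotype. Adgre1 was at -1.19 in WT and 0.28 in KO, Ctss at -1.29 and 0.92, and Itgam at 3.05 and -0.88. The cell cycle list had a median of 0.17 (adjusted p = 0.00180, but adjusted p = 0.608 with an estimated correlation) and the glycolysis list one of 0.16 (adjusted p = 0.0382, but adjusted p = 0.679 with an estimated correlation). Without the array labelled KO at 24 h the NF-kB, cell cycle and glycolysis lists no longer passed (adjusted p = 0.443, 0.249 and 0.807). Their medians were then 0.33, which is larger, 0.12 and 0.076. Without KO 0 h array b the NF-kB (0.14, adjusted p = 0.0677) and glycolysis (0.17, 0.0712) lists did not pass, and without KO 0 h array a the glycolysis list (0.10, 0.233) did not. Without the WT 24 h array the cell cycle and glycolysis medians were 0.32 and 0.35. Mmp3 (2.18, SE 0.63), Birc3 (0.32, SE 0.23), Icam1 (0.21, SE 0.53), Tnf (-0.03, SE 0.29) and Sod2 (-0.09, SE 0.18) did not pass. Without the array labelled KO at 24 h Mmp3 was at 1.41, Birc3 at 0.54, Icam1 at -0.83 and Tnf at -0.34, and without the WT 24 h array Icam1 was at 1.25, Tnf at 0.28 and Birc3 at 0.093. Without the array labelled KO at 24 h, 72 genes passed. Without the WT 24 h array 3 did, among which Ccl2 was not (adjusted p = 0.0503), and without any 1 of the other 8 arrays Ccl2 alone.

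**Figure D2:**
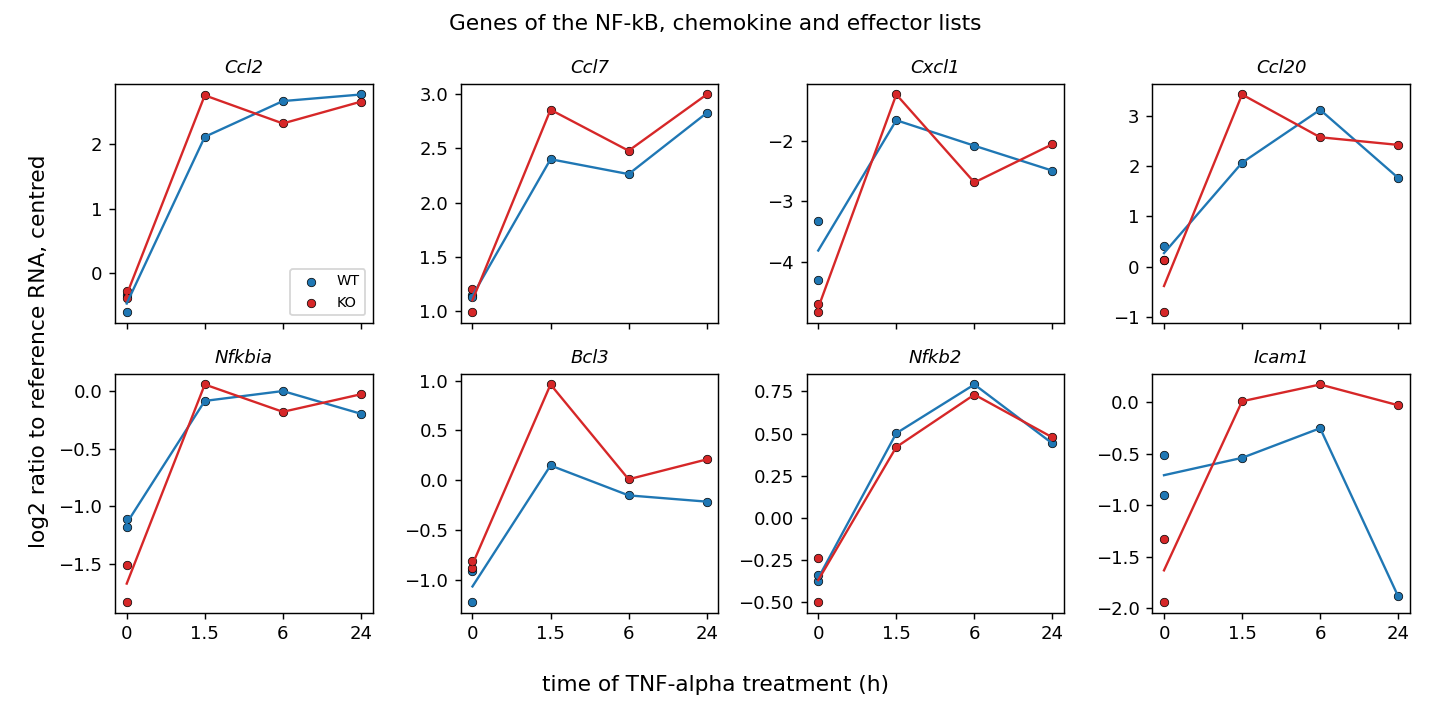
Centred log2 ratio to the reference RNA of 8 genes on each of the 10 arrays against hours of TNF-alpha treatment, with WT in blue, KO in red, 1 point per array and lines through the means. Ccl2 lies between -0.60 and -0.28 at 0 h and between 2.11 and 2.77 on the 6 treated arrays, the array labelled KO at 24 h included.

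The second question was which genes differed between KO and WT whatever the time. No gene passed the threshold in the genotype average (limma, 0 of 14365 genes). At an unadjusted p under 0.05 there were 1391, of which 608 were higher and 783 lower in KO. The list of cell cycle and DNA replication genes was lower in KO as a group, with a median of -0.27 and 40 of 43 members negative (camera adjusted p = 1.43e-09, but adjusted p = 0.0979 with an estimated correlation). Adjusted over the list alone, 6 of its members were lower, each at 4 of 4 times: the primase subunit Prim1 (-0.87, SE 0.19), the helicase subunit Mcm5 (-0.60, SE 0.13), cyclin A2, Ccna2 (-0.58, SE 0.13), the licensing factor Cdt1 (-0.54, SE 0.13), Birc5 and Cdk1. With quantile normalization Prim1 was at -0.48, Ccna2 at -0.38 and Cdt1 at -0.13, and after removal of the trend in spot order Cdk1 was at -0.24. The median of this list was -0.53 at 0 h, -0.33 at 1.5 h, -0.28 at 6 h and -0.18 at 24 h, the last drawn from the array labelled KO at 24 h. Skeletal and cardiac muscle markers were higher in KO, with a median of 0.42 and 17 of 17 members positive (camera adjusted p = 2.70e-09, and adjusted p = 0.0497 with an estimated correlation). The median was 0.51 at 0 h, 0.38 at 1.5 h, 0.27 at 6 h and, on the array labelled KO at 24 h, 0.60. Of the 17, 6 passed adjusted over the list alone, among them cardiac actin, Actc1 (0.88, SE 0.15), cardiac troponin T, Tnnt2 (0.85, SE 0.24, at 3 of 4 times, and 0.44 without the WT 24 h array and KO 0 h array b), the myosin light chain Mylpf (0.77, SE 0.13) and the slow troponin I, Tnni1 (0.62, SE 0.15). Ribosomal protein genes had a median of -0.20, with 51 of 60 negative (camera adjusted p = 2.01e-05, but adjusted p = 0.354 with an estimated correlation). Of them Rps24 (-0.79, SE 0.12, and -0.37 after removal of the trend in spot order) passed adjusted over the list alone. By fry the adjusted p was 0.0172 for the cell cycle list, 0.0105 for the muscle list and 0.0727 for the ribosomal list. The NF-kB, chemokine and effector lists did not pass by camera, with medians of 0.03, 0.07 and -0.10 and adjusted p values of 0.337, 0.209 and 0.477. Of their members Ikbke (0.60, SE 0.14) was higher in KO adjusted over the list alone. The image numbers in the labels run through the WT arrays before the KO arrays, so array order and genotype cannot be told apart. The KO 0 h arrays had the widest spread of values over spots (SD 0.833 and 0.983, against 0.551 to 0.827 on the others). Without KO 0 h array b 1 gene passed.

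**Figure D3:**
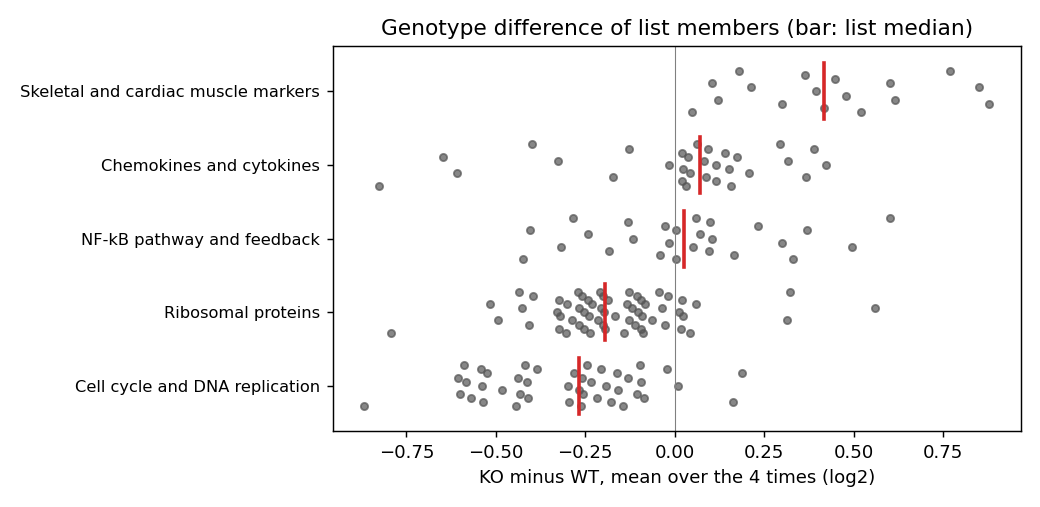
KO minus WT in the genotype average (log2), in which 0 h weighs more than each later time, of each measured member of 5 gene lists, 1 point per gene, with the list median as a red bar and points spread vertically for legibility. All 17 muscle markers lie above 0 with a median of 0.42, and 40 of 43 cell cycle genes lie below 0.

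The untreated samples, the only groups with 2 arrays each, were compared next. In the genotype at 0 h comparison no gene passed the threshold (limma, 0 of 14365 genes). At an unadjusted p under 0.05 there were 2464, of which 1100 were higher and 1364 lower in KO. Cell cycle genes were lower in KO (median -0.53, 37 of 43 negative, camera adjusted p = 3.04e-05) and muscle markers (0.51, adjusted p = 0.000735) and Hox genes (0.26, adjusted p = 0.00848) higher. Each had adjusted p = 0.497 with an estimated correlation. The cell cycle list no longer passed with quantile normalization (adjusted p = 0.296), nor the Hox list without KO 0 h array a (0.0824), where its median was 0.27. Chemokines and cytokines had no common direction (median 0.16, adjusted p = 0.882), but 4 were lower in KO adjusted over the list alone: Ccl5 (-2.26, SE 0.20, 4.79-fold), Ccl4 (-1.55, SE 0.35), Cxcl5 (-1.35, SE 0.25) and Tslp (-1.10, SE 0.19). With quantile normalization these were -1.04, -0.42, -0.099 and -0.057. Of the effectors, Lcn2 (-2.56, SE 0.71) and Mmp3 (-2.41, SE 0.49) had the largest values and did not pass. They were -3.66 and -1.67 without KO 0 h array a and -1.45 and -3.14 without array b, values that passed there (adjusted p from 0.000977 to 0.0370). In the insulin-like growth factor list Igf1 (-1.01, SE 0.19) and Igfbp4 (-1.0, SE 0.23) were lower and Igfbp5 (0.80, SE 0.20) higher, adjusted over the list alone. With quantile normalization Igf1 was at -0.65, Igfbp5 at 0.57 and Igfbp4 at 0.19, the reverse of its direction here. Without KO 0 h array a, 3264 genes passed, and without KO 0 h array b 472. In both cases the residual spread comes from the WT 0 h pair alone, with KO 0 h assumed to vary like it.

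The question of the design, whether the response to TNF-alpha differed by genotype, was tested as the interaction, which is positive where KO rose more than WT. The NF-kB, chemokine and effector lists did not pass at any time, with list medians between -0.18 and 0.21 and camera adjusted p values from 0.379 to 0.998. Of their members 1 passed adjusted over the list alone, the chemokine Ccl5 at 6 h (3.81, SE 0.34, 14.0-fold, and 2.35 with quantile normalization), which did not pass over all genes (adjusted p = 0.141). Its response at 6 h was 3.70 in KO and -0.12 in WT (SE 0.24 each), from a level at 0 h that was 4.79-fold lower in KO. Members that did not pass also had unlike responses at 6 h. Lcn2 was at -1.80 in WT and 3.20 in KO (SE 0.87 each) and Lbp at -1.25 and 1.94 (SE 0.53 each). In the other direction, Traf2 was at 0.76 and -0.65 (SE 0.40 each) and Mmp10 at 1.58 and 0.19 (SE 0.42 each). By fry, tested for change in either direction, the chemokine and effector lists passed at 6 h (adjusted p = 0.0320 each), as did 13 of the other 27 lists. Taken as 1 set of 85 genes, a set formed after the single lists were seen, their medians were 0.06 at 1.5 h, -0.01 at 6 h and 0.13 at 24 h (limma camera, adjusted p = 0.726, 0.805 and 0.408). By fry in either direction its adjusted p was 0.672, 0.0313 and 0.0726. The same set rose with TNF-alpha over the genotypes, with medians of 0.25, 0.28 and 0.19 (limma camera, adjusted p = 7.93e-09, 3.43e-13 and 0.000227). With an estimated correlation these were adjusted p = 0.0559, 0.0230 and 0.228. The medians were 0.11, 0.18 and 0.11 without KO 0 h array b, and the last was 0.29 without the WT 24 h array. Against 0 h the median of this set was 0.08 in WT and 0.32 in KO at 1.5 h. It was 0.27 and 0.38 at 6 h, and 0.17 and, on the array labelled KO at 24 h, 0.25 at 24 h. The interaction was positive in 48 of the 85 genes at 1.5 h, in 42 at 6 h and in 48 at 24 h. Ccl2 had close responses in both genotypes, with log2 2.58 in WT and 3.09 in KO at 1.5 h (SE 0.25 each), 3.14 and 2.65 at 6 h, and 3.24 and, on the array labelled KO at 24 h, 2.99 at 24 h. Other members did not. At 1.5 h Cxcl1 was at 2.15 in WT and 3.51 in KO (SE 0.43 each) and Ccl20 at 1.8 and 3.8 (SE 0.46 each), while Tnf was at 0.80 and -0.35 (SE 0.23 each). Icam1 had a larger value in KO at each time, with interactions of 1.48 (SE 0.50), 1.35 (SE 0.50) and 2.78 (SE 0.50) at 1.5, 6 and 24 h, none of which passed (adjusted p = 0.999, 0.337 and 0.182). Those at 6 and 24 h were 1.66 and 3.09 without KO 0 h array a, and that at 24 h was 2.48 without KO 0 h array b. Icam1 was lower in KO at 0 h by a value that did not pass either (-0.92, SE 0.29), and its WT value at 24 h against 0 h was -1.18 (SE 0.35), against 1.60 (SE 0.35) for the array labelled KO at 24 h.

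The genes past the threshold over all genes lay outside those lists. At 1.5 h 0 genes passed in the interaction (limma, 534 at an unadjusted p under 0.05). At 6 h 1 gene passed of 1991 at an unadjusted p under 0.05, the olfactory receptor Olfr741 (-8.83, SE 0.32, adjusted p = 0.00892). At 24 h, with the array labelled KO at 24 h, 4 passed of 1888: the keratin-associated gene Krtap31-1 (-8.92, SE 0.44), Cd83, a surface protein of activated dendritic cells (-6.25, SE 0.40), the protocadherin Pcdhb21 (-6.02, SE 0.32) and the olfactory receptor Olfr1491 (-5.15, SE 0.33). Each was measured by 1 probe and lay far above its other values on 1 WT array. Olfr741 was at 7.84 on the WT 6 h array and the other 4 between 5.50 and 7.70 on the WT 24 h array. Krtap31-1 was also at -3.15 on the array labelled KO at 24 h, which adds to its value. At 6 h the macrophage and haematopoietic marker list had a positive median (0.55, 16 of 17 positive, camera adjusted p = 0.000131), as had the interferon response list (0.46, adjusted p = 0.0481). The smooth muscle (-0.55, adjusted p = 0.0351) and Hox (-0.46, adjusted p = 0.0481) lists had negative ones. All 4 had adjusted p = 0.637 with an estimated correlation. Of the macrophage list 7 members passed adjusted over the list alone, among them Adgre1, the F4/80 antigen (3.52, SE 0.38), and the protease Ctss (3.46, SE 0.46), which were at 2.26 and 1.01 with arrays scaled to equal range. At 24 h the interferon (0.52) and Hox (-0.40) lists passed (each with adjusted p = 0.0204, but adjusted p = 0.682 with an estimated correlation), a direction drawn from the array labelled KO at 24 h. The interferon median turned to -0.40 at 6 h and -0.17 at 24 h with quantile normalization, and the smooth muscle median to 0.48 with arrays scaled to equal range. The macrophage list no longer passed under either (adjusted p = 0.701 and 0.848), nor did the Hox list at 6 h (0.329 and 0.213) or 24 h (0.0910 and 0.145). With quantile normalization the smooth muscle median was -0.12 (adjusted p = 0.984). The Hox median at 6 h was -0.15 after removal of the trend in spot order (adjusted p = 0.398), and the list did not pass with probes valued on at least 8 arrays (0.1001). Without KO 0 h array a neither the interferon and Hox lists (adjusted p = 0.0962 at 6 h and 0.0534 at 24 h) nor the smooth muscle list at 6 h (0.0840) passed. Their medians were then 0.59 and -0.43 at 6 h, 0.64 and -0.35 at 24 h, and -0.55 for smooth muscle. At 6 h the interferon list also failed without WT 0 h array b (0.47, adjusted p = 0.0649) or KO 0 h array b (0.24, 0.0944), as did the Hox list (-0.37, 0.0649, and -0.43, 0.0725) and, without WT 0 h array a, the Hox list (-0.44, 0.0636). The counts rested on the processing and on the 0 h arrays. At 24 h 0 genes passed with each probe alone and 44 with arrays scaled to equal range. Without KO 0 h array a 363, 2581 and 2004 genes passed at the 3 times, and without KO 0 h array b 42, 768 and 810 did. Without either WT 0 h array 0 passed at any time.

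Across the 14365 genes, the WT and KO responses had a Pearson r of 0.09 (Spearman 0.11) at 1.5 h, -0.38 (-0.38) at 6 h and -0.11 (-0.12) at 24 h, the last with the array labelled KO at 24 h. With 1 of the 0 h arrays left out r ranged from -0.061 to 0.24 at 1.5 h, from -0.41 to -0.22 at 6 h and from -0.14 to -0.030 at 24 h, with the ends set by KO 0 h arrays a and b. In the 85 genes of the 3 TNF-alpha target lists r was 0.64 (0.40), 0.12 (0.07) and 0.45 (0.27). Genes are not independent replicates. Each of these 6 correlations rests on 1 treated array per genotype, so no p is given.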

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

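The tests in this part were chosen before their outcomes were seen, except the Sirt6 test of swapped 6 h labels and the test of extreme values on WT arrays alone, whose thresholds were set after the values were known. The first 2 patterns and the values at the end come from the interaction or the responses of each genotype, and the third pattern comes from the genotype average.

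The 5 genes past the threshold in the interaction had values of -8.83 (Olfr741, at 6 h), -8.92 (Krtap31-1), -6.25 (Cd83), -6.02 (Pcdhb21) and -5.15 (Olfr1491, these 4 at 24 h), each from 1 probe far above its other levels on 1 WT array, while Krtap31-1 was also at -3.15 on the array labelled KO at 24 h. As the source of such values in both directions together a response to TNF-alpha, which needs treated arrays, is argued against, since of 119 probe values over 4 log2 units from the median of the other arrays 41.2% (exact 95% interval 32.2 to 50.6) were on the 4 arrays at 0 h, 14 and 32 of these 49 on KO 0 h arrays a and b. Only 4 of those 14 and 8 of those 32 were upward, against 24 of 33 on the WT 24 h array. For upward values, the direction of the 5 genes, a response to TNF-alpha was not tested apart. On the WT arrays alone it stays open, with 6.12% of 49 at 0 h (1.28 to 16.9, exact) and 33 on the WT 24 h array. Faulty single spots are a candidate explanation, since in genes with more than 1 probe only 8.45% of 71 such values (3.17 to 17.5, exact) were followed by the gene's other probes. The 5 genes themselves have no other probe, so whether their values are faulty was not tested directly, and a change in the WT samples stays open.

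At 6 h the WT and KO responses ran opposite across genes (r = -0.38, -0.41 to -0.22 with 1 of the 0 h arrays left out), with positive interactions of the macrophage (0.55) and interferon (0.46) lists. Swapped 6 h labels are argued against by Sirt6, where KO minus WT at 6 h was -1.23 (SE 0.30). However, only 43.1% of 225 genes apart by genotype at the other times kept their direction at 6 h (36.6 to 49.9, exact, with genes on 1 pair of arrays counted as independent). A swap is therefore less than excluded. The choice of the 225 genes used the array labelled KO at 24 h, so the doubt about its label extends to this share. A wider range of values on some arrays may account for the list results, since the macrophage and interferon medians lay at the 35.6th and 32.7th percentiles of 10000 random lists matched on mean log ratio, so that genes of like level shifted as much. For the correlation itself range stays open, as it was -0.28 after each array was scaled to equal range (-0.34 to -0.14 with 1 of the 0 h arrays left out), and so does position on the array, as it was -0.28 after removal of the local trend in spot order (-0.29 to -0.20), intervals that reach across the bound set for each. A difference between the genotypes in how these genes respond is also open and rests on 1 treated array each.

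Cell cycle genes were lower (-0.27) and muscle markers higher (0.42) in KO in the genotype average. A difference in array range is argued against for the muscle list, whose median lay at the 100th percentile of matched random lists. The cell cycle median lay at the 0.11th percentile, but range may account for part of it. Its matched lists also shifted down (-0.205 to -0.0028). Quantile normalization took its median at 0 h from -0.53 to -0.17 (camera adjusted p = 0.296). Random lists do not allow for list members that vary together. A broad trend in spot order is argued against for the cell cycle list, which kept 93.5% of its median after removal of that trend. It stays open for the muscle list, which kept 72.1%. Other effects of position stay open for both lists, since neighbouring spots still varied together after the removal. Their correlation was then 0.052 on the WT 6 h array (0.083 before) and 0.22 on WT 0 h array a (0.58 before), the lowest and highest of the 10 arrays. Chance is not excluded. Of 100 splits of the 10 arrays into groups of 5, 20 gave a cell cycle median as large in size (highest other 0.44). A muscle median as large came from 16 (highest other 0.60), and as many genes at an unadjusted p under 0.05 from 18 (1391, highest other 2454). Splits that do not balance the times hold less information on the difference. Of the 19 drawn that do, the real one included, 1, 2 and 3 gave values as large. For genes past the adjusted threshold the splits decide nothing, since the real count was 0 and all 100 reach it (highest other 399). The 3 splits with 399 genes put both arrays of each treated time on 1 side. They are 1 fit of KO 0 h array b against the other 3 arrays at 0 h and show that array standing apart. A difference in the origin of the samples, array order and an effect of Sirt6 loss cannot be told apart, since all 3 run with the genotype. The origin was not tested, and sex-linked genes leave it open. At 0 h Uty was higher in KO (1.25, SE 0.30, past the threshold over its list alone by limma). Zfy1 was lower, at -0.82 and -1.59 in KO and -0.09 and -0.43 in WT. Within WT, Uty was at -1.01 and -1.13 at 0 h and at 0.03, 0.52 and 0.25 at 1.5, 6 and 24 h.

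In the interaction at 6 h the smooth muscle list had a median of -0.55 and the Hox list one of -0.46. At 24 h, from the array labelled KO at 24 h, the interferon list had a median of 0.52 and the Hox list one of -0.40.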

How the results depend on the processing

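The cell cycle and muscle lists in the genotype average (medians from -0.41 to -0.14 and from 0.30 to 0.55), the chemokine lists at each time, the NF-kB lists at 1.5 and 6 h and the 85 TNF target genes together in the TNF responses (0.11 to 0.39 at 1.5 h, 0.16 to 0.37 at 6 h, 0.11 to 0.29 at 24 h) kept their direction and their side of the threshold in all 19 alternatives, read at the preset correlation and for the 85 genes at an unadjusted camera p. Counts of genes are given below as genes past the threshold, and the cause of a change was not tested unless stated. Values without centring shift the median of all genes to -0.20 at 0 h by genotype and to 0.23 and 0.26 in the interactions at 6 and 24 h. They gave 1 gene at 0 h by genotype, 1 each in the TNF responses at 6 and 24 h, 3 and 37 in the interactions at 6 and 24 h, and medians of the 85 genes of -0.045 in the genotype average and 0.25 in the interaction at 6 h. Quantile normalization gave 2 genes in the genotype average and 27 in the interaction at 24 h, medians of the 85 genes of 0.091 at 0 h and 0.080 in the genotype average, which passed at an unadjusted camera p (0.0476 and 0.0176), and of -0.055 and -0.13 in the interactions at 1.5 and 24 h, an effector median of -0.0026 at 1.5 h, and interferon interactions of -0.40 and -0.17 at 6 and 24 h. With values on at least 8 arrays the 85 genes had a median of 0.0017 at 0 h. Each probe alone gave a median of 0.019 for the 85 genes at 0 h, 1, 1, 2 and 0 genes in the TNF responses at 6 and 24 h and the interactions at 6 and 24 h, and an interferon interaction of -0.011 at 6 h, with more features tested. The genes with an SD above the median gave -0.30 for the ribosomal list, which no longer passed (adjusted p = 0.110), 1 gene each in the TNF responses at 6 and 24 h and the interaction at 24 h, and 0.10 for the 85 genes in the interaction at 6 h. With letters a and b as a replicate block, 0 genes passed in the genotype average, at 0 h by genotype, in the 3 TNF responses and in the interactions at 1.5 and 24 h, 1 in the interaction at 6 h, and the effector median was -0.024 at 1.5 h. In this setting the treated arrays, which have no letter, were placed with the a arrays. The TNF responses then compare them with the a arrays alone. The letters are not shared across genotypes in the values, since the deviations of same-letter arrays had a correlation of -0.0053. An adjusted p under 0.1 gave 1 gene in the genotype average and 29 in the interaction at 24 h. The model with 1 mean per group gave 0, 1 and 5 genes in the TNF responses, and 1 average interaction over the 3 times gave 0 genes (limma, 1548 at an unadjusted p under 0.05). Of the alternatives chosen after seeing the data, removal of the trend in spot order gave 2 genes in the genotype average, 4 and 1 in the TNF responses at 1.5 and 6 h, and -0.0069 and 0.051 for the 85 genes in the genotype average and the interaction at 6 h. Scaling to equal range gave 2 genes in the genotype average, 1 and 4 in the TNF responses at 6 and 24 h and 44 in the interaction at 24 h, 0.041 at 0 h and -0.0025 in the interaction at 24 h for the 85 genes, 0.48 for the smooth muscle and -0.35 and -0.056 for the interferon interactions at 6, 6 and 24 h, and a correlation of responses at 6 h of -0.28. Array weights gave 2 genes in the genotype average and 3, 1 and 1 in the TNF responses. Without the WT 24 h array and KO 0 h array b the counts were 472 at 0 h by genotype, 0, 0 and 13 in the TNF responses and 42 and 768 in the interactions at 1.5 and 6 h, where the spread comes from fewer arrays, and the 85 genes had 0.066 at 0 h. With each array left out in turn the counts ranged from 0 to 1 in the genotype average, from 0 to 3264 at 0 h by genotype, from 0 to 4, 0 to 9 and 1 to 72 in the TNF responses and from 0 to 363, 2581 and 2004 in the interactions. The medians of the 85 genes ranged from -0.033 to 0.037 in the genotype average, from -0.12 to 0.066 at 0 h and from -0.052 to 0.080 in the interaction at 6 h, that of the muscle list in the TNF response at 6 h from -0.33 to 0.034, and the correlation of responses from -0.061 to 0.24 at 1.5 h and from -0.41 to -0.22 at 6 h. Further lists lost their pass with their direction kept. In the interactions at 6 and 24 h these were the Hox list with quantile normalization, equal range and genes with an SD above the median (adjusted p from 0.0545 to 0.329), and at 6 h also with values on at least 8 arrays (0.1001), without the trend in spot order (-0.15, 0.398) and without the WT 24 h array and KO 0 h array b (0.0725). The smooth muscle list did so with quantile normalization (-0.12, 0.984), and the interferon list with genes with an SD above the median (0.243 and 0.110), at 24 h with each probe alone (0.128) and at 6 h without the WT 24 h array and KO 0 h array b (0.0944). In the TNF responses these were the immediate early and smooth muscle lists at 1.5 h in 6 alternatives each (0.0843 to 0.781), the muscle list at 6 h in 4 (0.227 to 0.398), the cell cycle list at 6 h in 7 (0.0689 to 0.909), the glycolysis list at 24 h in 5 (0.0516 to 0.458) and the NF-kB list at 24 h with letters as a block (0.122). Of 5728 values of named genes under the alternatives 77 turned sign, 71 lost and 238 gained a pass. After these were first seen, a gene past the threshold in neither setting was judged by its size and not its sign. Neither signal over background nor spot quality is used here, so what they limit is not known.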

Other observations

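In the insulin-like growth factor list, in the genotype average, the receptor Igf1r (-0.83, SE 0.16) and the binding protein Igfbp4 (-0.75, SE 0.15) were lower in KO at 4 of 4 times, adjusted over the list alone, while Igf2 (0.62, SE 0.20, 4 of 4 times) and Igfbp5 (0.66, SE 0.17, 3 of 4 times) were higher. With quantile normalization Igf2 was at -0.23, the reverse of this direction, and Igfbp4 at -0.28. The time of 24 h in these counts is drawn from the array labelled KO at 24 h. Among epithelial markers the tight junction gene Ocln (0.73, SE 0.20) and the keratin Krt7 (0.65, SE 0.16) were higher, as were Laptm5 (0.81, SE 0.16) and Tyrobp (0.49, SE 0.13) of the macrophage list, adjusted over the list alone. After removal of the trend in spot order Ocln was at 0.49, Laptm5 at 0.32 and Tyrobp at 0.27.

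In the untreated samples 5 members of the interferon list were lower in KO and 2 higher, adjusted over the list alone. Ifit1 (-2.27, SE 0.28), Oasl2 (-1.88, SE 0.33), the peptide transporter Tap1 (-1.52, SE 0.23), the GTPase Igtp (-1.12, SE 0.21) and Dhx58 (-1.01, SE 0.20) were lower, and Rsad2 (1.02, SE 0.23) and Gbp2 (0.84, SE 0.21) higher. With quantile normalization Oasl2 was at -0.83, Tap1 at -0.85, Igtp at -0.094 and Dhx58 at -0.50, and after removal of the trend in spot order Rsad2 was at 0.37 and Gbp2 at 0.13. In the macrophage list 5 members were lower, among them Ctss (-1.36, SE 0.26), the Fc receptor subunit Fcer1g (-1.31, SE 0.30) and Adgre1 (-1.22, SE 0.22), and Laptm5 (1.08, SE 0.24) was higher. With quantile normalization Fcer1g was at -0.31 and Adgre1 at -0.13, with equal range Ctss at -0.091, and without the trend in spot order Laptm5 at 0.12. The smooth muscle list did not pass (median 0.07, camera adjusted p = 0.118, and adjusted p = 0.497 with an estimated correlation). Of its 12 members 4 were higher adjusted over the list alone: the smooth muscle myosin Myh11 (1.44, SE 0.22), desmin, Des (0.90, SE 0.24), smooth muscle actin, Acta2 (0.84, SE 0.21), and Lmod1 (0.67, SE 0.19). Acta2 was at -0.25 with quantile normalization and at -0.30 with arrays scaled to equal range, where Myh11 was at 0.58 and Lmod1 at 0.35. Adjusted over their own lists alone, elastin, Eln (1.24, SE 0.24), and the muscle regulator Myog (1.20, SE 0.22) were also higher, but Eln was at 0.39 with equal range and Myog at 0.38 without the trend in spot order. The kinase gene Pdk1 (-1.40, SE 0.22) and the epithelial protease gene St14 (-1.40, SE 0.21) were lower, and were at -0.16 and -0.53 with quantile normalization. The genes of both paragraphs were named after their values were seen, and none passed over all genes.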
